A study of Homo sapiens with 12 samples.

How the data were processed

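Cultured human lung fibroblasts were compared on 12 Affymetrix HG-U133 Plus 2.0 type arrays in 3 groups of 4 (control, Cr, SOV+Cr). Per the labels' protocols, cells grew in medium with 15% serum, total RNA had an RNA integrity number above 9.9, and 10 ug of it was labelled with biotin by the one-cycle method of the array's maker. Per the series' design text, each group holds 4 RNA extractions from 4 different cultures. The deposited values are one linear signal intensity per probe set and array, as the values themselves show; the software that summarised the probes, the background correction and any scaling are not given in the sources used here. The intensity values ran from 0.019 to 15975, and no 2 arrays were copies: at most 0.00366% of probe sets had identical values on 2 arrays, and the highest correlation of log2 values between 2 arrays was 0.9364.

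Intensities were turned to log2(value + 1). The medians of the 12 arrays spanned 1.04 on that scale, over the limit of 0.3 set before the data were examined, so limma quantile normalization between arrays was used for all results. Fold changes are therefore on the log2(value + 1) scale after quantile normalization, so for genes with a group mean under the filter below the size of a change depends on the constant added. Before normalization the median signal per array ran from 10.7 to 23.1. The 9 hybridization control probe sets, which report material added after labelling, averaged 9.71 to 10.4 on the log2 scale. Array weights estimated by limma were 1.64 to 2.5 for the bright arrays and 0.322 to 0.633 for the dim arrays.

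Of the 54675 probe sets, 62 are control probe sets. The array annotation, dated 2016, gave 1 gene symbol to 41097 probe sets, several to 1801, and did not list 11777. Of the single-symbol probe sets, 41043 matched the RefSeq table of assembly GRCh38.p14 by gene number, from which current symbols were taken; no coordinates were used, and gene length was taken from the same table. A gene was represented by its probe set with the highest mean over the 12 arrays, so another probe set of the gene can differ. The report gives opposite signs of other probe sets beside the reported fold changes of named genes, not beside values under other settings. Genes whose mean lay above the 40th percentile of all probe sets (3.18 on the log2 scale) were tested, 13876 in all. Probe sets with no single symbol were tested apart, 6073 of them. Y-linked genes and XIST were not reported.

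All tests used limma 3.58.1 in R 4.3.3. One model with a coefficient per group was fitted to all 12 arrays (lmFit and eBayes, 9 residual degrees of freedom), with the contrasts Cr minus control, SOV+Cr minus control and SOV+Cr minus Cr. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The 25 gene lists and 6 marker lists were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison; the same test with the correlation estimated for each list, and fry, were alternatives. fry asks whether a list's genes move on balance one way, or in its mixed form in either direction, and does not compare the list with other genes. List members are counted as adjusted over all genes and as adjusted over the list alone. Shifts within the bright or dim arrays are means over a list's genes, and values with ± are SE of a log2 fold change or, where stated, SD. Figures were drawn with matplotlib 3.10.9.

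Genes named in the text follow a rule set before the data were examined: per comparison, up to 8 called genes in each direction with the largest fold change whose groups do not overlap; up to 3 called members of each list; the 9 genes PLK1, CDKN1A, MDM2, CCND1, HMOX1, MT2A, COL1A1, DUSP6 and PTPN1, called or not; and, since fewer than 5 genes were called, the 5 genes with the smallest p in each direction. This gave 36 genes. Examples given for a list that the rule does not name were chosen after their values were seen, among the members with the smallest p or those that went against the list.

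Replicate numbers in the labels are shared by the groups, so it was checked whether arrays of one number deviate together from their group means. The correlation of these deviations between arrays of the same number was 0.217 to 0.418 for control and Cr and 0.30 to 0.401 for Cr and SOV+Cr, above the 0.1 needed in every pair, and these arrays were taken as paired by number. The labels do not say what a number stands for. Part of the correlation comes from the bright and dim sets, since these follow the numbers, so the check cannot tell pairs from these sets. Over all 3 groups, 4 of 12 arrays were closest to their own number in both other groups. Pairs in the text are therefore arrays of equal number, and a true pairing was not established. For control and SOV+Cr the lowest correlation was 0.0622, and these arrays share only a number. The planned fit has no block; a fit with the replicate number as a block is given where it changes a call in the paired comparisons. The bright and dim sets, found after the data were seen, were treated as a technical batch: results are given with them as a block and within each set.

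Alternatives chosen in advance were no normalization between arrays, median centring, pseudocounts of 16 and 64, no filter and a filter at the 60th percentile, other rules for several probe sets of a gene, eBayes with trend and robust, array weights, the replicate block, a fit of only the groups compared, stricter thresholds, and leaving out each of the 12 arrays in turn. Added after seeing the data were the bright and dim block, each set of arrays alone, and the replicate block joined with pseudocount 16, with trend and robust, with fry, or with an estimated list correlation, the last also with the bright and dim block.

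The fits were tested on simulated data with 13876 genes, 200 of them changed. The simulated arrays held the difference between bright and dim arrays, which the fit without a block leaves in the spread. For Cr against control, SOV+Cr against control and SOV+Cr against Cr the fit recovered 14.0%, 14.0% and 13.8% of genes changed by 1 log2 unit, 69.6%, 71.0% and 65.6% of those changed by 2, and 91.4%, 93.2% and 90.6% of those changed by 3. A list shifted by 0.3 was found in 9, 10 and 10 of 10 simulations, with 0, 0 and 1 of 240 unshifted lists called. Genes were simulated independently of each other, so these list counts do not cover lists whose genes move together. In the data the estimated correlation was 0.37 for mitotic and 0.16 for replication and G1/S genes. Comparisons that share arrays were set against 50 simulations of unchanged groups.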

Results

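Gene expression was measured in cultured human lung fibroblasts, the connective-tissue cells that make most of the lung's collagen, after exposure to hexavalent chromium. The 12 arrays fell into 3 groups of 4: cells kept in medium (control), cells given 1 uM chromate for 24 h (Cr), and cells given 10 uM of the compound that the labels call SOV 30 min before 1 uM chromate for 24 h (SOV+Cr). Hexavalent chromium enters cells as chromate, is reduced there, and damages DNA. The title of the series names inhibition of PTPs, the protein tyrosine phosphatases, which remove phosphate from tyrosine residues. A group given SOV alone was not analysed here, so SOV+Cr against control holds the joint effect of both compounds. The design text states that the 4 arrays of a group came from 4 RNA extractions of 4 separate cultures.

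Each array held one linear signal per probe set. The median signal was 20.1 to 23.1 on replicates 1 and 2 of every group and 10.7 to 14.2 on replicates 3 and 4 of every group, which are called the 6 bright and the 6 dim arrays here. This split was balanced over the groups, and values within each set of arrays stand beside the comparisons. The ACTB control probe sets gave a 3' minus 5' difference of 2.26 on the log2 scale on SOV+Cr replicate 4 and of -0.05 to 0.84 on the other 11 arrays. The number of arrays limits the precision, and so does the bright and dim split, which the fit without a block leaves in the spread. In simulated data with 4 arrays per group and that split, the fit recovered 14.0% of genes changed by 1 log2 unit for Cr against control. It recovered 69.6% of genes changed by 2. With the replicate number as a block these were 26% and 80.2%, with 6.18% of calls false against 2.558% without the block.

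**Figure D1:**
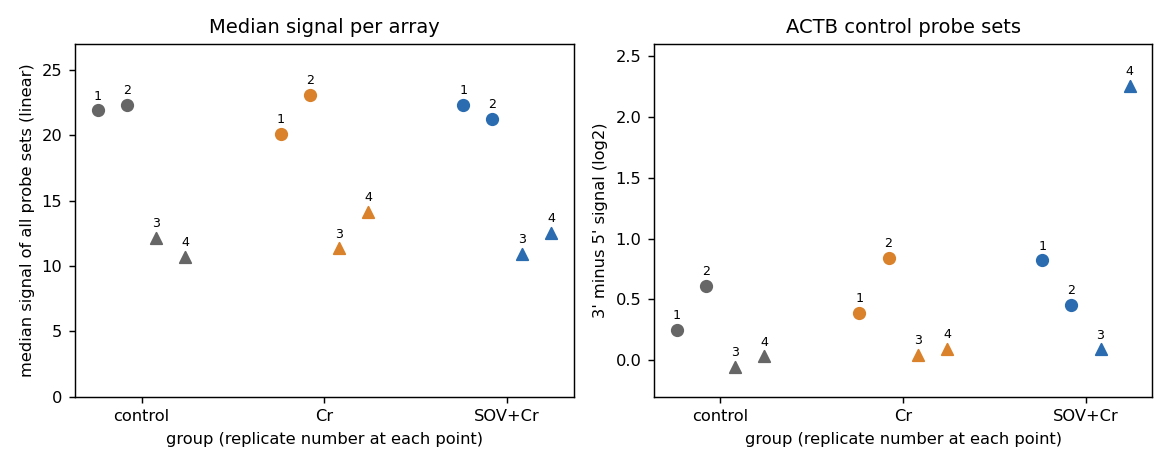
Left, the median linear signal of each of the 12 arrays by group; right, the difference between the 3' and 5' ACTB control probe sets on the log2 scale; points carry replicate numbers, circles are replicates 1 and 2, triangles replicates 3 and 4. Medians lie at 20.1 to 23.1 for the circles and 10.7 to 14.2 for the triangles in all 3 groups, and SOV+Cr replicate 4 has the highest ACTB difference, 2.26.

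The cultures carried the marker profile of fibroblasts. The 12 fibroblast markers had a median log2 signal of 11.5, at the 98.7th percentile of all genes, with VIM, the intermediate filament protein of mesenchymal cells, highest at 13.2. Median log2 signals were 3.0 for 14 epithelial markers, 3.33 for 10 endothelial markers, 2.88 for the 10 blood cell markers on the array and 2.69 for 6 mesothelial markers, between the 21.3rd and the 32.0th percentile. The 10 smooth muscle and pericyte markers stood at 7.61, led by ACTG2 at 12.4. The smooth muscle and pericyte markers, not tested as a list and summarised after the data were seen, had a median log2 fold change of -0.45 in both Cr and SOV+Cr against control (-0.25 and -0.40 without normalization between arrays). With limma 0 markers passed in any comparison, and few or no genes passed at all.

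Chromate alone changed no single gene past the threshold, while 7 of the 25 fixed lists passed with camera at the preset correlation. Another split of the same arrays gave 8 lists, so chance was not excluded for that count. The shifts of lists described below carry that limit. Of 13876 genes tested with limma for Cr against control, 0 had an adjusted p under 0.05, and 539 had an unadjusted p under 0.05 where chance gives 693.8. The smallest adjusted p was 0.321, shared by genes that were all lower after chromate, none of which passed. TLN2, which encodes the adhesion protein talin 2, had a mean log2 signal of 5.79 ± 0.09 (SD, n = 4) in Cr and 6.86 ± 0.20 in control, 2.11-fold lower. MYH11, the smooth muscle myosin heavy chain, was 2.84-fold lower, although 1 of its 7 probe sets, of low signal, had 1.55, and PRKG1, the cGMP-dependent protein kinase, was 2.64-fold lower. Among genes that were higher, GDAP2 had a 2.00-fold, the histone gene H2AC25 a 1.85-fold and LEISA1 a 2.09-fold difference. Their other probe sets did not follow, at -0.01 for GDAP2, -0.20 for H2AC25 and -0.31 and -0.19 for LEISA1. For 4 further genes a group mean lay under the filter of 3.18, so the size of the difference depends on the constant added before the log: LYG1 had -2.01 (-0.99 with pseudocount 16), CELA3A -1.92 (-0.82), BATF2 1.82 (0.65) and VPS13A-AS1 1.78 (0.69). Fits with the replicate number or the bright and dim sets as a block also called 0 genes, with 1056 and 911 genes at an unadjusted p under 0.05. Array weights, which count the dim arrays less, called 17 genes, 3 higher and 14 lower.

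DNA replication genes fell as a group after chromate. The 36 tested replication and G1/S genes had a median log2 fold change of -0.35, with 29 below 0 (camera adjusted p = 7.93e-08; adjusted p = 0.128 with an estimated correlation), and their mean shift was -0.40 on the bright and -0.35 on the dim arrays. Adjusted over the list alone, 3 members fell and 0 rose: MCM6, a subunit of the replicative helicase, by 0.87 ± 0.18 (SE) on the log2 scale, GINS2 by 0.91 ± 0.22, and CDC6, which loads that helicase, by 1.07 ± 0.27. With the replicate block 8 members fell over the list alone. The 38 mitotic genes rose as a group in the same comparison, with a median of 0.29 and 36 members above 0 (adjusted p = 1.03e-07; adjusted p = 0.346 with an estimated correlation). Their mean shift was 0.42 on the bright and 0.19 on the dim arrays, and 0 members passed adjusted over the list alone. NEK2 and CCNB1, the mitotic cyclin B1, had log2 fold changes of 0.70 ± 0.23 and 0.72 ± 0.37. With the replicate block 3 mitotic members rose over the list alone. Without Cr replicate 1 the mitotic median was 0.18. Over all other settings the replication median ran from -0.42 to -0.15 and the mitotic median from 0.18 to 0.51.

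Damage and stress response groups rose after chromate as well. The 32 tested p53 target genes had a median log2 fold change of 0.27 with 27 above 0 (camera adjusted p = 7.63e-07; adjusted p = 0.0297 with an estimated correlation), with mean shifts of 0.26 on the bright and 0.20 on the dim arrays. The death receptor FAS had 0.70 ± 0.22 and CDKN1A, the cell cycle inhibitor p21, had 0.42 ± 0.19 with all 4 Cr arrays above all 4 control arrays. Neither gene passed over all genes or over the list alone; with the replicate block 1 p53 target, FAS, did over the list alone (adjusted p = 0.0125). NRF2 target genes, which make glutathione and other antioxidant proteins, had a median of 0.24 with 28 of 30 above 0 (adjusted p = 0.000341; adjusted p = 0.0297 with an estimated correlation) and mean shifts of 0.23 on the bright and 0.24 on the dim arrays. With an estimated correlation that call was lost under the replicate block (0.083) and the bright and dim block (0.0574). GCLM, a subunit of the enzyme that starts glutathione synthesis, had 0.36 ± 0.15 and HMOX1, heme oxygenase 1, 0.60 ± 0.31. Hypoxia and glycolysis genes had a median of 0.26 with 25 of 32 above 0 (adjusted p = 0.000379; adjusted p = 0.0297 with an estimated correlation), with shifts of 0.20 and 0.24 on the bright and dim arrays. KDM3A had 0.66 ± 0.21, and the glucose transporter gene SLC2A1 went against the list at -0.42 ± 0.20. No member of the NRF2 or hypoxia list passed alone. Without Cr replicate 4 the NRF2 median was 0.14. Over all other settings the median ran from 0.214 to 0.472 for p53 target, 0.141 to 0.462 for NRF2 target and 0.181 to 0.465 for hypoxia genes.

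Matrix and secretory pathway groups fell after chromate. Collagen and matrix genes had a median log2 fold change of -0.17 with 38 of 44 below 0 (camera adjusted p = 0.000379; adjusted p = 0.128 with an estimated correlation) and mean shifts of -0.26 on the bright and -0.22 on the dim arrays. FBN2, which encodes fibrillin 2, had -0.84 ± 0.21 and COL5A1 -0.72 ± 0.20, and 0 members passed over the list alone, against 4 that fell with the replicate block. Chaperone genes of the endoplasmic reticulum had a median of -0.17 with 18 of 22 below 0 (adjusted p = 0.0044; adjusted p = 0.346 with an estimated correlation) and shifts of -0.27 and -0.21 on the bright and dim arrays. HSPA5, the main chaperone of that compartment, had -0.52 ± 0.24. Without normalization between arrays the medians of these 2 lists turned to 0.01 for collagen and 0.06 for the chaperones while the median of all genes moved to 0.16, so their direction is relative to the other genes. The chaperone call was lost without normalization (median 0.06, adjusted p = 0.0985), with median centring (median 0.00, 0.0779) and with _x_at and _s_at probe sets left out (0.0977). It was also lost without control replicate 3 (0.128), control replicate 4 (0.0509), Cr replicate 1 (0.162) or Cr replicate 2 (0.0745). Single arrays also moved the size of these shifts: the collagen median was -0.25 without control replicate 3 and -0.11 without Cr replicate 4, and the chaperone median -0.27 without Cr replicate 3.

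In all, 7 of the 25 fixed lists passed the threshold for Cr against control, 4 up and 3 down. Of these, 3 passed with an estimated correlation and 0 with a directional fry test. The exact permutation p of the 7, over free splits of the 8 arrays and unadjusted, was 0.0571 to 0.171. In 2 combinations added after the data were seen, the replicate block with an estimated correlation passed 4 of the 7 and the replicate block with fry all 7. The 4 were p53 target (adjusted p = 0.0315), hypoxia (0.0288), replication (0.00855) and chaperone genes (0.0431). With the replicate block an eighth list, contractile and SRF target genes, passed as well (adjusted p = 0.00269 against 0.0649 without it; median -0.15), but not when the correlation was also estimated (adjusted p = 0.502 with an estimated correlation). In this comparison the 8 smooth muscle and pericyte markers outside that list had a median of -0.45, with 7 below 0. With the bright and dim sets as a block 8 lists passed, and 0 did when the correlation was also estimated. The other 18 lists had adjusted p from 0.0649 to 0.788 and medians from -0.15 to 0.21. They were DNA break and crosslink repair, excision and mismatch repair, metallothionein and zinc, heat shock, ATF4 target, MAPK feedback and immediate-early, contractile and SRF target, TGF-beta target, inflammatory and NF-kB target, interferon-stimulated, matrix protease and inhibitor, cholesterol synthesis, protein tyrosine phosphatase, BCL2 family, insulin and growth factor signalling, ribosomal protein, proteasome and respiratory chain genes. Among repair genes BRIP1, a helicase of crosslink repair, fell by 0.90 ± 0.18 adjusted over its list alone (adjusted p = 0.010). The list itself did not pass (median -0.07, 23 members below 0 and 12 above, camera adjusted p = 0.112). ADAMTS2, which trims procollagen, fell by 0.77 ± 0.18 over the matrix protease list alone (adjusted p = 0.0294).

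**Figure D2:**
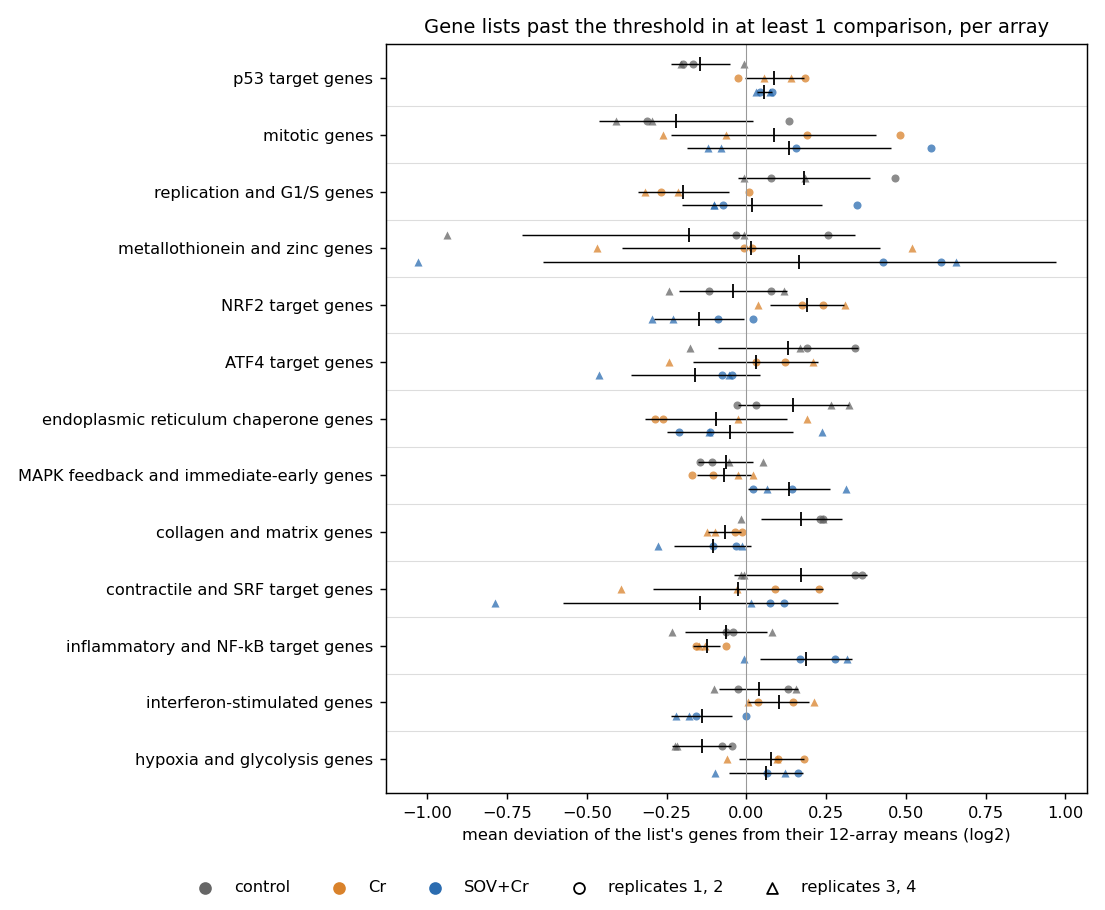
Mean deviation of each list's genes from their 12-array means (log2, x axis) for each array, for the 13 lists past the threshold in at least 1 comparison; colours are groups, circles replicates 1 and 2, triangles replicates 3 and 4, and bars the mean and SD of 4 arrays. NRF2 target genes have group means of 0.19 in Cr, -0.04 in control and -0.15 in SOV+Cr, and metallothionein and zinc genes spread from -1.03 to 0.66 within SOV+Cr.

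In SOV+Cr against control, RCC1 and SPMIP1 rose past the threshold and 0 genes fell. RCC1 encodes the nucleotide exchange factor that loads Ran with GTP at chromatin. Its log2 signal was 9.86 ± 0.25 (SD, n = 4) in SOV+Cr and 7.94 ± 0.12 in control, a 3.78-fold rise (log2 fold change 1.92 ± 0.20 SE, limma adjusted p = 0.00786), with 2.17 on the bright and 1.67 on the dim arrays, and its other probe set moved the same way. SPMIP1 rose from a low signal of 2.43 ± 0.95 to 5.75 ± 0.26, a log2 fold change of 3.32 ± 0.42 (adjusted p = 0.0307), with 3.08 on the bright and 3.56 on the dim arrays. The control mean lies under the filter of 3.18, so that size depends on the constant added: it was 1.72 with pseudocount 16 and 0.78 with pseudocount 64, both past the threshold. With the replicate block RCC1 kept its call (adjusted p = 0.0228) and SPMIP1 missed the threshold (0.0926), though control and SOV+Cr arrays share only a number. Both kept their call with the bright and dim sets as a block, which called 5 genes in all. Both lost it without normalization between arrays (adjusted p = 1 for RCC1 and 0.169 for SPMIP1) and with only the 2 groups compared (0.0798 and 0.183). RCC1 also lost it with the mean of all probe sets (0.0508). RCC1 missed the threshold without control replicate 1 (adjusted p = 0.0614), SOV+Cr replicate 1 (0.0628) or SOV+Cr replicate 2 (0.0544). SPMIP1 missed it without control replicate 1 (0.117) or 3 (0.0559), Cr replicate 2 (0.0527) or 4 (0.0501), or SOV+Cr replicate 1 (0.108), 2 (0.0763), 3 (0.0518) or 4 (0.0678).

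Further genes of this comparison had small p-values without passing. AOC2 was 2.26-fold higher (adjusted p = 0.0803), and LINC-PINT, a long noncoding RNA, 3.04-fold higher (0.106). The log2 fold change of AOC2 was 1.18, and over all other settings, other constants among them, it ran from 0.351 to 1.39. For 3 genes a group mean lay under the filter: LINC00622 had 3.15 (adjusted p = 0.123), FGA, the fibrinogen alpha chain, -1.93 (0.106) and TLCD1 -2.34 (0.106), and with pseudocount 16 they had 1.80, -0.81 and -1.28. LINC00622 and TLCD1 passed the threshold with that pseudocount. COX20, an assembly factor of cytochrome c oxidase, was 1.99-fold lower (0.157), CTNS, the lysosomal cystine transporter, 2.64-fold lower (0.181) and TMEM63A 2.48-fold lower (0.283). Other probe sets had the opposite sign for FGA (0.36), CTNS (0.61) and TMEM63A (0.57). In all, 970 genes had an unadjusted p under 0.05 where chance gives 693.8.

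In the combined treatment p53 target and mitotic genes were above control too. Cr and SOV+Cr are both compared with the same 4 control arrays. Chance in those arrays alone may therefore move a list the same way in both comparisons, which was not tested for lists. The p53 target genes rose, with a median log2 fold change of 0.27 and 24 of 32 above 0 (camera adjusted p = 0.0012; adjusted p = 0.106 with an estimated correlation), and shifts of 0.25 on the bright and 0.16 on the dim arrays. SPATA18 had 0.90 ± 0.24 and FAS 0.69 ± 0.22. The p53 call was lost with _x_at and _s_at probe sets left out (adjusted p = 0.153). Mitotic genes rose with a median of 0.35 and 34 of 38 above 0 (adjusted p = 3.29e-06; adjusted p = 0.437 with an estimated correlation), with shifts of 0.46 on the bright and 0.25 on the dim arrays. BUB1, a spindle checkpoint kinase, had 0.97 ± 0.29 and AURKA 0.71 ± 0.25, while the proliferation marker MKI67 went the other way at -0.39 ± 0.24. Without SOV+Cr replicate 1 the mitotic median was 0.18. Replication and G1/S genes fell with a median of -0.16 and 23 of 36 below 0 (adjusted p = 0.0408; adjusted p = 0.512 with an estimated correlation), with -0.14 on the bright and -0.19 on the dim arrays. That last call was lost with the bright and dim sets as a block (adjusted p = 0.0778) and without control replicate 1 (0.416) or 3 (0.16) or SOV+Cr replicate 2 (0.302), 3 (0.102) or 4 (0.0748). It was lost as well without normalization (0.102), with median centring (0.0605), no filter (0.0511), the filter at the 60th percentile (0.0634), the mean of all probe sets (0.0613) and array weights (0.0733). Its median was -0.09 without SOV+Cr replicate 2 or 4 and -0.25 without control replicate 2 or SOV+Cr replicate 1.

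Immediate-early and MAPK feedback genes rose in SOV+Cr over control, and matrix, contractile and ATF4 target genes fell. MAPK feedback and immediate-early genes had a median log2 fold change of 0.17 with 22 of 36 above 0 (camera adjusted p = 0.00237; adjusted p = 0.106 with an estimated correlation), with shifts of 0.21 on the bright and 0.19 on the dim arrays. EGR1, an immediate-early transcription factor, had 0.97 ± 0.35, KLF4 0.78 ± 0.25 and SPRY2, a feedback inhibitor of the pathway, 0.67 ± 0.27. Hypoxia and glycolysis genes rose with a median of 0.19 and 21 of 32 above 0 (adjusted p = 0.00999; adjusted p = 0.106 with an estimated correlation; 0.17 on the bright and 0.23 on the dim arrays), with VEGFA at 0.73 ± 0.30. Collagen and matrix genes fell with a median of -0.19 and 37 of 44 below 0 (adjusted p = 0.00144; adjusted p = 0.162 with an estimated correlation; -0.30 and -0.26). ATF4 target genes, which serve amino acid supply and transfer RNA charging, fell with a median of -0.31 and 27 of 33 below 0 (adjusted p = 0.00144; adjusted p = 0.437 with an estimated correlation; -0.33 and -0.25). AARS1, the alanyl-tRNA synthetase, had -1.05 ± 0.26. Contractile and SRF target genes fell with a median of -0.24 and 22 of 25 below 0 (adjusted p = 0.00237; adjusted p = 0.453 with an estimated correlation; -0.25 and -0.37), led by CNN1 at -1.20 ± 0.45. The smooth muscle and pericyte markers moved with this list, with a median of -0.45 and 8 of 10 below 0. Of these markers 2, ACTG2 and CNN1, are also in the list, and the other 8 had a median of -0.29 with 6 below 0. The contractile call was lost without SOV+Cr replicate 4 (median -0.11, adjusted p = 0.17), the array with the high ACTB 3' minus 5' difference; without it the ATF4 median was -0.17. The contractile median was -0.40 without SOV+Cr replicate 1, -0.39 without SOV+Cr replicate 2 and -0.37 without control replicate 4. The MAPK median was 0.25 without SOV+Cr replicate 3.

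Interferon-stimulated genes fell in SOV+Cr against control with a median of -0.20 and 20 of 30 below 0 (camera adjusted p = 0.029; adjusted p = 0.106 with an estimated correlation), with -0.13 on the bright and -0.23 on the dim arrays. IFI35 had -0.99 ± 0.30, and MX2 went against the list at 0.79 ± 0.37. The call was lost without control replicate 3 (adjusted p = 0.163) or SOV+Cr replicate 1 (0.0556) or 3 (0.0507, median -0.05), with no filter (0.0749), with _x_at and _s_at probe sets left out (0.0587) and with array weights (0.0548). Without control replicate 1 the median was -0.30. Metallothionein and zinc genes rose with a median of 0.34 and 11 of 11 above 0 (adjusted p = 0.029; adjusted p = 0.453 with an estimated correlation), with 0.41 on the bright and 0.29 on the dim arrays. The member that rose over the list alone was the zinc importer gene SLC39A10 (0.77 ± 0.18, adjusted p = 0.00937), whereas MT2A, the main metallothionein, had 0.18 ± 0.44. That list's call was lost with the bright and dim sets as a block (adjusted p = 0.0507) and with the filter at the 60th percentile (0.0514). The shift depends on single arrays: without control replicate 4 the median was -0.002 (adjusted p = 0.3), and without SOV+Cr replicate 1, 2 or 4 it was 0.14 (0.0604), 0.07 (0.154) or 0.09 (0.17), while it was 0.77 without SOV+Cr replicate 3 and 0.53 without control replicate 1. In total 10 lists passed, 5 up and 5 down, 0 with an estimated correlation. A directional fry test passed 4 of them, p53 target, MAPK, collagen and interferon-stimulated genes. The other 15 lists had adjusted p from 0.0754 to 0.893. Among them the inflammatory and NF-kB list passed fry (adjusted p = 0.0319) and had 2 members that rose over the list alone, PTGS2 by 1.69 ± 0.44 and TNFAIP3 by 0.78 ± 0.21 on the log2 scale (adjusted p = 0.0365 for both).

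SOV+Cr against Cr compares cells given SOV before chromate with cells given chromate alone. Since SOV alone was not analysed, an effect of SOV itself cannot be told apart from a change in the response to chromate. RCC1 and KCNQ5 rose past the threshold and 0 genes fell. RCC1 was at 9.86 ± 0.25 (SD, n = 4) in SOV+Cr and 8.19 ± 0.29 in Cr, a 3.19-fold rise (log2 fold change 1.67 ± 0.20 SE, limma adjusted p = 0.0298; 1.93 on the bright and 1.42 on the dim arrays). KCNQ5, a potassium channel gene, rose from 3.47 ± 0.40 to 5.25 ± 0.26 (1.78 ± 0.23, adjusted p = 0.0298; 2.15 and 1.42), but its other probe set, of lower signal, had -0.35. With the replicate block KCNQ5 missed the threshold (adjusted p = 0.0622), RCC1 kept it (0.034) and SIGLEC15 passed it (0.034); with the bright and dim sets as a block 9 genes passed, 5 higher and 4 lower. Both calls were lost without normalization between arrays (adjusted p = 1 for each), with median centring (0.0797 for each) and with only the 2 groups compared (0.238 for each). KCNQ5 also lost its call with pseudocount 16 (0.0614), pseudocount 64 (0.116, log2 fold change 0.46), _x_at and _s_at probe sets left out (0.0579) and trend and robust (0.0845). The RCC1 call was lost without control replicate 1 (adjusted p = 0.0827), 2 (0.082) or 3 (0.0692), Cr replicate 1 (0.161), 2 (0.0887) or 4 (0.0862), or SOV+Cr replicate 1 (0.136) or 2 (0.108). The KCNQ5 call was lost without control replicate 1, 2 or 3 (0.0827, 0.082 and 0.0692), Cr replicate 1, 2 or 3 (0.161, 0.101 and 0.182), or SOV+Cr replicate 1, 2 or 3 (0.136, 0.116 and 0.0605).

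Next in this comparison, without passing, SIGLEC15 was 3.53-fold higher and LYG1, with a Cr mean under the filter, had 2.25 (1.17 with pseudocount 16; adjusted p = 0.0668 for both genes). The cytokine IL11 was 2.43-fold higher, at 10.6 ± 0.24 against 9.30 ± 0.33 (adjusted p = 0.14); over the list of TGF-beta target genes alone IL11 rose (adjusted p = 0.00299). On the lower side CTNS was 2.94-fold, PARD6A 2.99-fold, CDADC1 2.37-fold and NDE1 2.31-fold lower, each at an adjusted p of 0.113, and NBPF20 was 2.23-fold lower (0.13). Sizes depend on the constant added for genes above the filter too. Over all other settings, other constants among them, PARD6A ran from -1.76 to -0.425 against -1.58 on the log2 scale. SIGLEC15 ran from 0.543 to 1.97 against 1.82. Of the 4 CDADC1 probe sets 3 were lower and 1, of low signal, had 1.04. The other NDE1 probe sets did not follow: with the mean of all its probe sets the log2 fold change was 0.03 against -1.21. In all, 759 genes had an unadjusted p under 0.05 where chance gives 693.8.

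**Figure D3:**
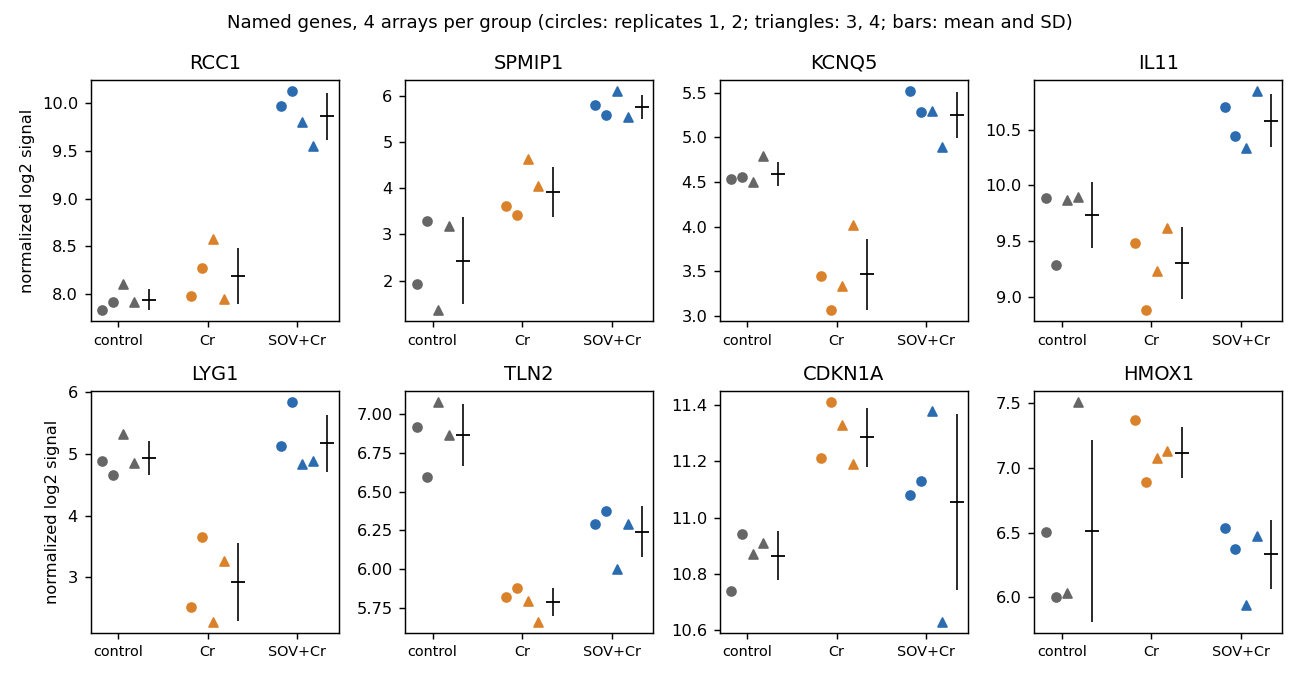
Normalized log2 signal (y axis) of 8 genes on each of the 4 arrays per group; circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the mean and SD. RCC1 stands at 9.86 in SOV+Cr against 7.94 in control and 8.19 in Cr; TLN2, LYG1, IL11, CDKN1A and HMOX1 did not pass the threshold over all genes in any comparison.

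Antioxidant genes fell when SOV was added to chromate. NRF2 target genes had a median log2 fold change of -0.28 with 25 of 30 below 0 (camera adjusted p = 0.000174, adjusted p = 0.0444 with an estimated correlation). Their shift was -0.24 on the bright and -0.44 on the dim arrays, and scores were lower in SOV+Cr in 4 of 4 pairs. The exact permutation p, over free splits of the 8 arrays and unadjusted, was 0.0286, two-sided, the smallest such splits can give. Those splits leave the pairs and the bright and dim sets aside. The interferon-stimulated and the inflammatory and NF-kB lists had the same exact permutation p. OSGIN1 had -1.92 ± 0.71, HMOX1 -0.78 ± 0.31 and GCLM -0.42 ± 0.15, and the transporter gene ABCC3 went against the list at 0.84 ± 0.23. With an estimated correlation the NRF2 call was lost when a block was added (adjusted p = 0.0838 with the replicate block, 0.0635 with the bright and dim block). No member passed over the list alone; with the replicate block 1 rose and 4 fell. Interferon-stimulated genes fell with a median of -0.30 and 22 of 30 below 0 (adjusted p = 0.00575; adjusted p = 0.0444 with an estimated correlation; -0.17 on the bright and -0.31 on the dim arrays), with IRF1 at -0.48 ± 0.19. That call was lost with the mean of all probe sets (0.0726), and with an estimated correlation it was lost under the replicate block (0.0798) and the bright and dim block (0.0635). The median was -0.19 without SOV+Cr replicate 3. ATF4 target genes fell with a median of -0.14 and 23 of 33 below 0 (adjusted p = 0.0195; adjusted p = 0.58 with an estimated correlation; -0.14 and -0.24), with ATF3 at -0.60 ± 0.18 and AARS1 at -0.81 ± 0.26. The ATF4 call was lost without Cr replicate 2 (median -0.06, adjusted p = 0.0926) or 3 (-0.09, 0.231) or SOV+Cr replicate 4 (-0.04, 0.228), and with _x_at and _s_at probe sets left out (0.0752). Without Cr replicate 4 the median was -0.29.

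Immediate-early, inflammatory and replication genes rose when SOV was added. MAPK feedback and immediate-early genes had a median of 0.16 with 26 of 36 above 0 (camera adjusted p = 0.00575; adjusted p = 0.0444 with an estimated correlation; 0.22 on the bright and 0.19 on the dim arrays). With an estimated correlation that call was lost under the replicate block (0.0918) and the bright and dim block (0.0635). EGR1 had 1.22 ± 0.35 and HBEGF, a ligand of the EGF receptor, 0.54 ± 0.18; neither passed over the list alone, and EGR1 did with the replicate block (adjusted p = 0.0408). Inflammatory and NF-kB target genes had a median of 0.19 with 18 of 24 above 0 (adjusted p = 0.0257; adjusted p = 0.088 with an estimated correlation; 0.33 and 0.29), with IL6 at 1.11 ± 0.36, PTGS2, which encodes cyclooxygenase 2, at 1.29 ± 0.44 and TNFAIP3 at 0.74 ± 0.21; these 3 passed over the list alone with the replicate block and 0 without it. That call was lost without Cr replicate 1 (adjusted p = 0.0558) or SOV+Cr replicate 2 (0.0533) and with _x_at and _s_at probe sets left out (0.153). Without SOV+Cr replicate 1 the median was 0.29, and without SOV+Cr replicate 3 the MAPK median was 0.26. Over all other settings the inflammatory median ran from 0.06 to 0.32 and the MAPK median from 0.03 to 0.26. Replication and G1/S genes rose with a median of 0.25 and 25 of 36 above 0 (adjusted p = 0.00995; adjusted p = 0.58 with an estimated correlation; 0.27 and 0.16), with MCM6 at 0.48 ± 0.18; the call was lost without Cr replicate 2 (0.116) or SOV+Cr replicate 1 (median 0.16, 0.227), and without normalization (median 0.08, 0.0784). In total 6 lists passed, 3 up and 3 down, 3 with an estimated correlation and 4 with a directional fry test. With an estimated correlation and either block 0 passed. Fry with the replicate block, a test added after the data were seen, passed 5 of the 6, all but ATF4 target genes (adjusted p = 0.104). The replicate block added a list, matrix protease and inhibitor genes (adjusted p = 0.0452 against 0.17; median 0.20), but not when the correlation was also estimated (adjusted p = 0.182 with an estimated correlation). The other 19 lists had adjusted p from 0.137 to 0.976, and the 28 tested protein tyrosine phosphatase genes had a median of 0.16 (adjusted p = 0.137). The median, the mean and the direction of the test differed in sign in 3 lists for Cr against control, 2 for SOV+Cr against control and 4 for SOV+Cr against Cr, none of them past the threshold; for Cr against control these were the MAPK, matrix protease and growth factor signalling lists.

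The comparisons were also set against each other. With limma 0 genes passed in Cr against control, so no called gene could be turned back with SOV or shared by both treatments, and such overlaps were not tested. At an unadjusted p under 0.05, 134 genes were turned back against 4 that moved further the same way, and 157 genes had the same sign in both treatments; array weights gave 2 turned back and 4 in both. Both pairs of comparisons share arrays, which alone can give such a pattern. Counts at an unadjusted p were not simulated, so how far sharing accounts for these was not tested. Fold changes of Cr and SOV+Cr over control had a correlation across genes of 0.52 where simulated unchanged groups gave 0.50, and a covariance of 0.085 where simulation gave 0.078; with the control arrays split between the comparisons the correlation was 0.04 to 0.09. Fold changes of Cr over control and SOV+Cr over Cr had a correlation of -0.36 against -0.50 in simulation, and -0.04 to 0.10 with the Cr arrays split. Genes are not independent replicates in these correlations.

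Of the 9 genes named in advance whatever their result, 0 passed the threshold over all genes in any comparison. DUSP6, a phosphatase that shuts off ERK, had 0.68 ± 0.29 in Cr and 0.68 ± 0.29 in SOV+Cr against control. MDM2, the p53 ubiquitin ligase, had 0.39 ± 0.45 and 0.59 ± 0.45, and its 10 probe sets differed in sign. PLK1, a mitotic kinase, had 0.42 ± 0.50 in Cr and -0.02 ± 0.50 in SOV+Cr, where the bright arrays gave 0.78 and the dim arrays -0.82. COL1A1, the collagen I chain, had -0.14 ± 0.22 and -0.19 ± 0.22, CCND1, cyclin D1, 0.01 ± 0.17 and 0.14 ± 0.17, and PTPN1, a tyrosine phosphatase, 0.26 ± 0.25 and 0.22 ± 0.25. In Cr against control other probe sets had the opposite sign for COL1A1 (0.01) and PTPN1 (-0.57). In SOV+Cr against control they did for PTPN1 (-0.19 and -0.05). COL1A1 was represented by its brightest probe set, and its others differed in size. In Cr against control these others had 0.01, -0.27, -0.51 and -0.32. In SOV+Cr against control they had -0.05, -1.11, -0.97 and -0.58. Without normalization between arrays COL1A1 turned to 0.01 in Cr against control.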

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

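Of the tests in this part, those of the bright and dim arrays, the splits balanced over these sets and the count of splits for genes changed in Cr against control were chosen after the result was seen. Single arrays stood far from the other 3 of their group in 12 of 162 groups of values tested, where chance gives about 8.1 (1 in 20), so a part of them is what chance alone gives.

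Among genes, PTPN1 was at 7.038 on control replicate 4 against 6.345 to 6.446 on the other control arrays, and IL11 at 9.288 on control replicate 2 against 9.867 to 9.892. TLCD1 was at 5.321 on Cr replicate 2 against 4.429 to 4.52. In SOV+Cr, MT2A was at 11.35 on replicate 3 against 13.15 to 13.24, CELA3A at 3.165 on replicate 2 against 3.974 to 4.113, COX20 at 8.308 on replicate 2 against 8.056 to 8.076, and SIGLEC15 at 6.088 on replicate 4 against 5.337 to 5.436 (all log2).

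Among lists, the collagen and matrix score was -0.01747 on control replicate 3 against 0.2297 to 0.2397 on the other control arrays. In SOV+Cr the replication and G1/S score was 0.3458 on replicate 1 against -0.1023 to -0.07307, and the metallothionein and zinc score -1.03 on replicate 3 against 0.4277 to 0.6563. SOV+Cr replicate 4 stood apart in the ATF4 target score, at -0.4615 against -0.07739 to -0.04529, and in the contractile score, at -0.7867 against 0.01589 to 0.1181. That array also has the ACTB 3' minus 5' difference of 2.26. Without it the ATF4 target genes in SOV+Cr against Cr had a median of -0.04 (adjusted p = 0.228) and the contractile genes in SOV+Cr against control -0.11 (adjusted p = 0.17). No biological explanation was tested for these arrays.

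Probe sets without a single gene name also gave a signal. Of 6073 tested with limma, 5 rose in SOV+Cr against control and 1 rose in SOV+Cr against Cr. The first of these by p rose by 4.41 ± 0.42 (SE, log2; adjusted p = 0.000867), and the one in SOV+Cr against Cr by 2.13 ± 0.28 (adjusted p = 0.033). In Cr against control 0 passed, with 238 at an unadjusted p under 0.05.

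The counts of called genes and lists were set against all 35 splits of the 8 arrays compared. For SOV+Cr against control the 10 called lists were reached by 1 split, the real one (highest other 7). That share is under 0.05, the limit set in advance, but it is the smallest that 35 splits can give. Free splits also mix bright and dim arrays, and several counts were tested this way without adjustment. Only 18 of the 35 splits keep 2 bright and 2 dim arrays on each side (1 of these with 10 lists, highest other 6). These are too few for a share under 0.05, and 0 lists passed with an estimated correlation, so chance stays open for that count. Chance cannot be excluded for the next 4 counts over free splits. The 7 lists of Cr against control were reached by 2 splits (highest other 8), and the 6 lists of SOV+Cr against Cr by 3 (highest other 6). The 2 genes of SOV+Cr against control were reached by 4 splits (highest other 7), and the 2 of SOV+Cr against Cr by 2 (highest other 2). Among the 18 balanced splits, 1 reached 2 genes in each of these comparisons, the real one (highest other 1), too few splits for a share under 0.05. For lists, 2 of the 18 reached the count in Cr against control (highest other 8) and 2 in SOV+Cr against Cr (highest other 6). For Cr against control, where limma called 0 genes and 539 had an unadjusted p under 0.05, all 35 splits reach that count by construction, so they say nothing about it. The split into bright and dim arrays gave 932 genes there, 7 in SOV+Cr against control and 0 in SOV+Cr against Cr. The count of 932 points to a structure other than treatment. The lower counts with SOV+Cr arrays do not show that these arrays lack it. The axis along which the 12 arrays spread most, the first principal component, held 28.5% of the variance. On it replicates 1 and 2 of every group lay below 0 and replicates 3 and 4 above 0. In SOV+Cr they lay at -36.6 and -35.4 against 39.5 and 25.1. With the bright and dim sets as a block the treatments gave 0, 5 and 9 genes in Cr against control, SOV+Cr against control and SOV+Cr against Cr. For the 2 comparisons with paired numbers, 8 splits part all 4 pairs; among these the highest other counts were 5 lists and 0 genes for Cr against control and 2 lists and 1 gene for SOV+Cr against Cr.

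Replicates 1 and 2 were bright and replicates 3 and 4 dim in every group, with log2 medians differing by 0.82. Treatment is argued against, since each group holds 2 arrays of either kind. A scanner setting or the staining is argued against too: the hybridization controls differed by 0.0652 ± 0.135 (SE) between the sets, where such a cause would move them by about as much as the medians. The amount or labelling of the RNA target cannot be told apart from other causes before hybridization, since the medians differ by 0.821 but the labelled amount is not given in the sources used here.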

How the results depend on the processing

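Of the alternatives in this part, the bright and dim block, each set of arrays alone and the combinations with the replicate block were chosen after seeing the data. In all, 30 planned and 8 added settings were run. For the 36 named genes, 57 results gave 1613 values, of which 1437 kept direction and side of the threshold, 53 lost and 66 gained the threshold, and 57 changed sign. For the 23 called lists, 670 of 828 values kept both, 158 lost the threshold and 0 changed the direction of the test. Of 268 counts 196 stayed within 1.5 times the reported count, many of them counts reported as 0 or counts of lists. The number of called genes stayed so in 10 of 32 settings for SOV+Cr against control and 4 of 32 for SOV+Cr against Cr. RCC1 kept its call in 20 of 28 values against control and 15 of 28 against Cr. SPMIP1 kept it in 15 of 28 and KCNQ5 in 8 of 27. The cause was not tested for any of the changes below, except that fewer arrays give less precision by construction.

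Counts of called genes are given next for SOV+Cr against control and then SOV+Cr against Cr, where 2 and 2 are reported. They were 0 and 0 without normalization between arrays, 2 and 0 with median centring, 6 and 1 with pseudocount 16, 3 and 1 with pseudocount 64, 5 and 4 with no filter, 1 and 1 with the filter at the 60th percentile, and 1 and 4 with the mean of all probe sets of a gene. They were 6 and 0 with _x_at and _s_at probe sets left out, 6 and 0 with every probe set tested, 2 and 1 with trend and robust, 0 and 0 with only the 2 groups compared, and 1 and 0 at an adjusted p under 0.01. Leaving out 1 array gave 0 to 6 and 0 to 4. For Cr against control limma called 0 genes in these settings (539 at an unadjusted p under 0.05). Array weights called 17 genes in Cr against control, 90 and 48 in the others, 2 turned back and 4 in both.

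The replicate block gave 0 genes in Cr against control, 3 in SOV+Cr against control and 2 in SOV+Cr against Cr. Control and SOV+Cr arrays share only a number: the lowest correlation of their deviations was 0.0622. Over all 3 groups, the paired ones included, 4 of 12 arrays were closest to their own number in both other groups. There SPMIP1 missed the threshold with that block (adjusted p = 0.0926), RCC1 kept it (0.0228) and LINC00622 passed it (0.0498). In SOV+Cr against Cr KCNQ5 missed it (0.0622) and SIGLEC15 passed it (0.034). With pseudocount 16 as well, the replicate block gave 0, 45 and 29 genes, and with trend and robust 12, 57 and 43, with 2 turned back and 3 in both. The bright and dim block gave 0, 5 and 9. The bright arrays alone and the dim arrays alone each gave 0, 0 and 0, with 2 arrays per group.

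Counts of called lists, for Cr against control, SOV+Cr against control and SOV+Cr against Cr, were 7, 10 and 6 as reported. They were 3, 0 and 3 with the list correlation estimated, 0, 5 and 4 with fry and 0, 1 and 0 with mixed fry. With _x_at and _s_at probe sets left out they were 7, 8 and 4. They were 4, 0 and 0 with the replicate block and 0, 0 and 0 with the bright and dim block when the correlation was also estimated. The replicate block gave 8, 12 and 6 with fry and 9, 15 and 9 with trend and robust, and the dim arrays alone 6, 3 and 1. Leaving out 1 array gave 6 to 9, 8 to 11 and 4 to 8.

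Values that changed sign belong to genes that did not pass the threshold as reported. Without normalization between arrays COL1A1 in Cr against control was 0.0141 and CCND1 in SOV+Cr against Cr -0.042. For PLK1 in SOV+Cr against control pseudocount 16 gave 0.00301, with the replicate block too, and pseudocount 64 gave 0.0358; DUSP6 in SOV+Cr against Cr was 0.00357 with pseudocount 64. With the mean of all probe sets MDM2 was -0.0103 in SOV+Cr against control and -0.343 in SOV+Cr against Cr, where PTPN1 was 0.158 and NDE1 0.0342. With _x_at and _s_at probe sets left out MDM2 was -1.03 and -1.76, and FGA 0.36 in SOV+Cr against control. With array weights CCND1 and MT2A were -0.0519 in Cr against control, HMOX1 0.0884 and PLK1 0.594 in SOV+Cr against control, and DUSP6 0.169, MT2A 0.332, PLK1 0.03 and PTPN1 0.16 in SOV+Cr against Cr. On the bright arrays alone CCND1 was -0.0964 and MT2A -0.115 in Cr against control, HMOX1 0.21 and PLK1 0.766 in SOV+Cr against control, and DUSP6 0.311, MDM2 -0.182, MT2A 0.353, PLK1 0.0031 and PTPN1 0.208 in SOV+Cr against Cr. On the dim arrays alone PTPN1 was -0.028 in Cr and -0.315 in SOV+Cr against control, and in SOV+Cr against Cr CCND1 was -0.0505 and COL1A1 0.024.

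Leaving out 1 array gave, in Cr against control, -0.0264 to 0.0605 for CCND1, -0.232 to 0.0146 for COL1A1 and -0.11 to 0.347 for MT2A. In SOV+Cr against control it gave -0.353 to 0.151 for HMOX1, -0.156 to 0.619 for MT2A and -0.443 to 0.405 for PLK1. In SOV+Cr against Cr it gave -0.2 to 0.0683 for COL1A1, -0.174 to 0.262 for DUSP6, -0.104 to 0.545 for MDM2, -0.192 to 0.409 for MT2A and -0.17 to 0.143 for PTPN1. Sizes also moved without a change of sign. MDM2 ran from 0.0439 to 0.689 and PLK1 from 0.123 to 0.647 in Cr against control, and PTPN1 from 0.0934 to 0.407 in SOV+Cr against control. The called genes kept their direction: RCC1 had 1.83 to 2.02 against control and 1.58 to 1.79 against Cr, SPMIP1 2.97 to 3.6 and KCNQ5 1.64 to 1.97. Signal limits the values too: the dim arrays had medians of 10.7 to 14.2 and weights of 0.322 to 0.633.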

Other observations

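Of the tests in this part, those of long genes (except the test with second probe sets) and that of the Cr arrays within replicate numbers were chosen after the result was seen. Many genes longer than 200 kb were lower after chromate. Among genes with a mean log2 signal above 6, the 567 longer than 200 kb had a median log2 fold change of -0.23 in Cr against control, with 474 below 0, and the 5441 of 50 kb or less had 0.02. The median went from -0.07 for genes of 100 to 200 kb to -0.21 for 200 to 400 kb and -0.33 above 400 kb. In SOV+Cr against Cr the long genes stood 0.23 above the short ones, with 0.15, 0.19, 0.15 and 0.47 in the pairs. Both comparisons use the same Cr arrays, so chance in those arrays alone may give such opposite shifts. This was not tested for the long genes. In SOV+Cr against control the difference was -0.01, but this rests on 1 replicate number. Number 4, which holds the SOV+Cr array with the ACTB 3' minus 5' difference of 2.26, gave 0.32, and the other 3 gave -0.12, -0.16 and -0.10. It was -0.15 on the bright and 0.12 on the dim arrays.

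In Cr against control the long members had a lower median than the others in all 10 lists of the report that hold any, by amounts that were not tested. The 6 long collagen and matrix genes had a median of -0.50 and the other 38 -0.14. The 7 long protein tyrosine phosphatase genes had -0.37 and the other 21 had 0.03; the 3 long matrix protease genes had -0.77 and the other 24 had 0.06. The difference was smallest for contractile genes, with -0.153 for 4 long and -0.147 for 21 other members. The 1 long NRF2 target gene had 0.01 and the other 29 had 0.24. TLN2 (454 kb) and PRKG1 (1310 kb), which had among the smallest p after chromate, are long genes, as is KCNQ5 (577 kb), at -1.13 in that comparison. LINC-PINT (232 kb) went the other way, at 0.88. Another probe set, of lower signal, had the opposite sign for KCNQ5 (0.25) and for LINC-PINT (-0.37).

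For the lower long genes, several technical causes are argued against. The long-minus-short difference of -0.25 was reached by 1 of 35 splits, the real one (highest other 0.188), although only 8 of these part all pairs, too few for a share under 0.05. It was negative in all 4 pairs (-0.26, -0.33, -0.27 and -0.09), at -0.29 on the bright and -0.20 on the dim arrays. Among genes matched by expression level it was -0.238 ± 0.0521 (SE), and with the second probe set of each gene -0.173 ± 0.0405. RNA or cDNA integrity stays open, since the 2 control genes contradict each other. The ACTB 3' minus 5' difference was higher in Cr than in control by 0.131 ± 0.236 (SE), and in 4 of 4 pairs (SE of the pairs 0.0369). The GAPDH difference was -0.126 ± 0.0596, lower in 4 of 4 pairs (0.058). Blocked transcription through long genes may be the biological cause, with -0.325 for the longest genes, but no transcription rate was measured and it cannot be told apart from a change in RNA stability.

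NRF2 target genes rose with chromate and fell when SOV was added, and replication and G1/S genes did the opposite. Both comparisons use the same 4 Cr arrays, so chance in those arrays alone may give such opposite shifts. In an exact permutation test of the 4 Cr arrays against the other 8, over 495 splits and adjusted over 25 lists, p was 0.253 for NRF2 target genes (difference 0.29) and 0.379 for replication and G1/S genes (difference -0.30), so chance was not excluded. That test leaves the replicate numbers aside. Within each of the 4 numbers the Cr array had the highest NRF2 target score and the lowest replication score (exact permutation p = 0.0123 for each over 81 splits, two-sided, the smallest they can give; adjusted p = 0.103 over the lists), so chance was not excluded here either. The tyrosine phosphatase list had the same p. With the Cr arrays split between the comparisons the shifts had opposite signs in 4 of 4 splits for 8 of the 25 lists, these 2 among them: 0.15 to 0.32 and -0.42 to -0.25 for NRF2 target genes, and -0.47 to -0.28 and 0.12 to 0.31 for replication genes.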
